A study of Mus musculus with 11 samples.

How the data were processed

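RNA was sequenced from colonic epithelial cells enriched on Percoll, a density medium used here to remove lymphocytes, from wild-type (WT) mice and from mice that lack both the miR-181a1-b1 and the miR-181a2-b2 cluster (DKO). Per the labels' protocols, messenger RNA was enriched on oligo(dT) beads and libraries were made with the NEBNext Ultra II RNA kit by a sequencing provider. Per the submitters' processing notes, STAR and the mouse build mm10 were used. The version of STAR, the read counter, the gene annotation and the strand setting are not given in the sources used here. The deposited table holds raw counts per gene, with 1 column for each of the 11 libraries and no normalization, as its whole-number values and unequal column totals show. It has 54513 genes, identified by symbol or, where there is none, by Ensembl identifier, and all of its columns were matched to samples by name. Because the strand setting is not given, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical genes such as Sprr2a2 and its paralogs are uncertain.

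Libraries were grouped by the genotype and treatment in the labels, giving baseline WT (n = 2), baseline DKO (n = 3), DSS WT (n = 3) and DSS DKO (n = 3). The labels call the libraries biological replicates and do not say whether each came from 1 mouse, so p-values measure the spread between these samples. No 2 libraries of a group agreed within sampling noise, since the chi-square per degree of freedom between them was 15.9 to 897. Totals were 41631951 to 52761900 counts, and counting error was small beside the spread between libraries for all but genes with few counts.

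Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with edgeR's filterByExpr at a minimum count of 10, which left 19267 genes holding at least 99.9% of each library's counts, and libraries were scaled by TMM. A robust quasi-likelihood model with 1 mean per group was fitted to all 11 libraries together, with a common biological coefficient of variation of 0.234. Each comparison used the two-sided quasi-likelihood F-test with Benjamini-Hochberg adjustment at an adjusted p under 0.05. The comparisons were DKO against WT after DSS, DKO against WT at baseline, DSS against baseline in each genotype, and the interaction of genotype and treatment. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. CPM values are TMM-scaled, with means and SDs over the libraries of a group.

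The design, the tests, 46 gene lists from textbook knowledge of the colon, the other settings to try and the rule for naming genes were fixed before the data were examined. The 45 lists with at least 5 measured members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. The same test with an estimated correlation and fry, which asks whether a list's genes moved on balance one way, were run beside it. Adjusted p-values of lists were adjusted over all lists tested. Named genes were the 10 rising and 10 falling genes with the largest log2 fold change among those past the threshold, with a mean log2 CPM of at least 1 and groups that did not overlap; up to 4 called members of each list with the lowest adjusted p; the miR-181 host genes and published targets; and the 10 genes with the lowest p in the interaction. Unnamed gene models and receptor segments were passed over. Some genes that the rule allows are not reported here.

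Positions were taken from GENCODE M21 on GRCm38 (mm10) by symbol, which found 50671 of the 54513 genes (93.0%). The table holds identifiers newer than that annotation, so the annotation the authors counted with was another one. The longest annotated 3' UTR of each gene, of at least 100 bases, was searched for the miR-181 sites TGAATGT (7mer-m8), GAATGTA (7mer-A1) and TGAATGTA (8mer), and for 100 shuffled 7-mers as controls.

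The methods were tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 changed genes. In the simulated comparison of DKO and WT after DSS (19101 genes), 7.46% of genes changed 1.5-fold, 39.4% of genes changed 2-fold and 68.8% of genes changed 4-fold were recovered, with 7 false calls among 82. At baseline (19130 genes), the shares were 4.48%, 24.6% and 68.2%, with 2 false calls among 66. For DSS against baseline in WT (19087 genes) they were 1.49%, 22.7% and 77.3%, with 8 false calls among 75, and in DKO (19122 genes) 7.46%, 41.8% and 77.3%, with 8 among 92. In 3 of the 4 the false calls were above the nominal 5%. A list lowered 1.5-fold was found among 45 lists with both the preset and the estimated correlation, with 0 other lists past the threshold. The simulated genes were drawn independently of one another. This run therefore does not show how many false list calls arise when genes are correlated.

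Alternatives were DESeq2 size factors in the edgeR fit, no filter on low counts, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a 2-fold minimum, a fit to the libraries compared, the replicate number as a block, and leaving out each library in turn. Leaving out a baseline WT library leaves 1 in that group, which is then assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9.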

Results

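The series measured messenger RNA in Percoll-enriched colonic epithelial cells of WT and miR-181 DKO mice, untreated (baseline) or given 2% dextran sulphate sodium (DSS) for 7 days with 2 days of recovery. DSS is a sulphated polysaccharide that injures the colonic epithelium and causes colitis. The series title concerns the part of miR-181, a microRNA family, in inflammation of the colon. The 11 libraries comprised baseline WT (n = 2), baseline DKO (n = 3), DSS WT (n = 3) and DSS DKO (n = 3), with 41631951 to 52761900 counts each. On the first principal component (45.5% of the variance of log2 CPM) every baseline library lay between -75.1 and -51.0 and every DSS library between 28.2 and 79.3. On the second (16.6%), DSS WT lay between -52.9 and -44.9 and DSS DKO between 15.7 and 65.1.

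The targeted microRNA genes could not be checked with these libraries. Mir181a-1 and Mir181b-1, on chromosome 1 from 137966455 to 137966718, and Mir181a-2 and Mir181b-2, on chromosome 2 from 38852735 to 38853918, had 0 counts in all 11 libraries, as libraries of polyadenylated RNA are not made to hold them. Mir181a-1hg, the host transcript of the first cluster, had 4 to 31 counts, and its log2 fold change in DKO was 1.14 after DSS and 1.70 at baseline, with adjusted p = 0.124 and 1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Nr6a1, the gene that overlaps the second cluster, had log2 fold changes of 0.44 (adjusted p = 0.113) and -0.23 (adjusted p = 1) in the same test. The labels do not give the deleted bases, so these counts check nothing about the genotype.

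Library composition differed between groups in 2 further ways. Every baseline library had a male pattern of sex-linked genes and every DSS library a female one. Xist, the RNA that silences an X chromosome, was at 7.04 ± 0.416 CPM in baseline WT (SD, n = 2), 9.91 ± 4.08 in baseline DKO, 846 ± 61.8 in DSS WT and 686 ± 45.8 in DSS DKO (SD, n = 3 each). Ddx3y, a Y-linked gene, was at 53.5 ± 2.10 and 47.5 ± 4.94 CPM in baseline WT and DKO, and at 0.768 ± 0.161 and 0.182 ± 0.0208 CPM in DSS WT and DKO. Sex was therefore the same within each comparison of genotypes and differed in each comparison of DSS with baseline. Rn18s-rs5, an entry for 18S ribosomal RNA, took 23.05% of the counts in baseline DKO replicate 1 and 8.46% in replicate 2, against 0.128% to 1.59% in the other libraries.

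**Figure D1:**
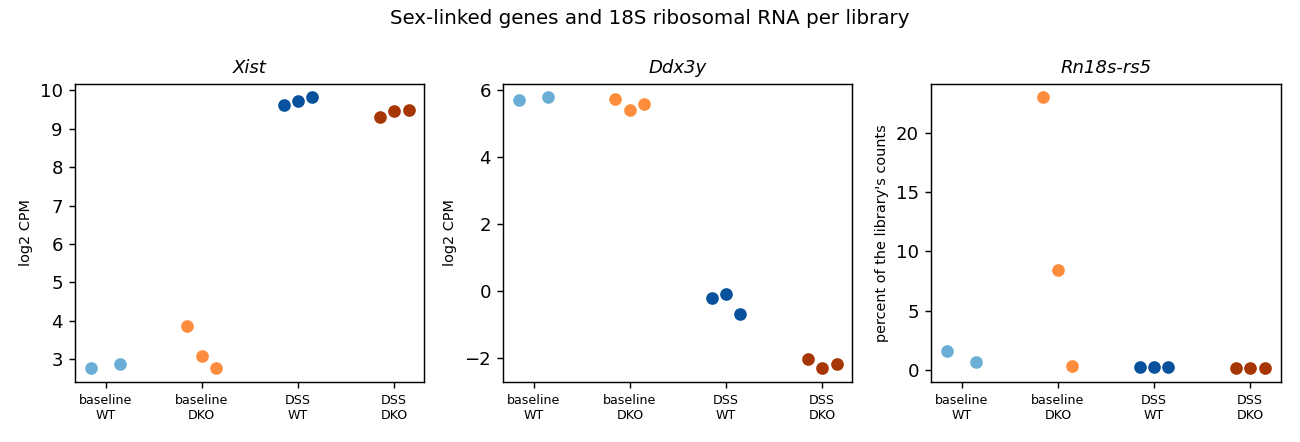
Log2 CPM of Xist and Ddx3y and the percentage of each library's counts assigned to Rn18s-rs5, with 1 point per library and libraries grouped by genotype and treatment on the x axis. Xist is low and Ddx3y high in all 5 baseline libraries, the reverse holds in all 6 DSS libraries, and Rn18s-rs5 reaches 23.05% and 8.46% in 2 baseline DKO libraries.

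After DSS, the lists of interferon-gamma, T cell and deep crypt secretory genes were lower in DKO than in WT, and those of matrix remodelling and neutrophils higher, by limma's camera at its preset correlation and not at an estimated one. Clca1, a goblet cell protein that processes mucus, was at 233 ± 33.6 CPM in DSS DKO and 2346 ± 263 in DSS WT (SD, n = 3 each). Mptx1, a secreted pentraxin of the crypt, was at 4.64 ± 1.45 and 338 ± 99.5 CPM. Slc9a3, the apical sodium-proton exchanger NHE3, was at 1088 ± 399 CPM in DSS DKO and 141 ± 13.8 in DSS WT. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2165 of 19267 genes passed, 1013 higher and 1152 lower in DKO. With a 2-fold minimum, 532 were higher and 394 lower. Without a strain label, a difference of strain background between the genotypes cannot be told apart from the deletion in these calls.

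Among genes that the naming rule takes by size of change, the largest increases were those of Zbtb16 (log2 fold change 4.27 ± 0.59, SE), Cyp3a25 (4.23 ± 0.61), Mmp13 (4.15 ± 0.98), Angptl4 (3.96 ± 0.64), Saa3 (3.79 ± 0.51), Tnc (3.23 ± 0.77), Cyp4b1 (3.02 ± 0.38), Slc9a3 (2.95 ± 0.23), Slc10a2 (2.90 ± 0.30) and Depp1 (2.79 ± 0.47). Mmp13 is a collagenase, Tnc the matrix protein tenascin C, Saa3 an acute-phase protein and Slc10a2 the apical bile acid transporter. The largest decreases were those of Mptx1 (-6.18 ± 0.38), Trpv6 (-4.75 ± 0.78), a calcium channel, Fut9 (-4.16 ± 0.47), a fucosyltransferase, Slc16a12 (-3.47 ± 0.34), Tmprss13 (-3.44 ± 0.42), Clca1 (-3.33 ± 0.17), Gal3st2c (-3.10 ± 0.46), Mcpt2 (-3.07 ± 0.57), a mucosal mast cell protease, and Ctse (-3.04 ± 0.36). The Y-linked gene Kdm5d also passed, at -3.25, but at trace levels of 0.0584 and 0.601 CPM, and 4 Y-linked genes are among the 1152 lower genes. Adjusted p-values of these genes in the edgeR test lay between 2.51e-06 for Clca1 and 0.0289 for Tnc. The calls of Mmp13 and Tnc were lost without DSS WT replicate 2 (adjusted p = 0.0965 and 0.0957), without DSS WT replicate 3 (0.0882 and 0.0856) and without DSS DKO replicate 2 (0.0698 and 0.0755). That of Mmp13 was also lost without DSS WT replicate 1 (0.0732), that of Tnc without baseline WT replicate 2 (0.0506), and that of Mcpt2 without DSS DKO replicate 2 (0.0541). A fit to the 6 DSS libraries alone also ended those of Mmp13 (0.0571) and Tnc (0.0505).

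In DKO after DSS, of 12 measured genes of deep crypt secretory cells, which support the colonic stem cells, 0 were higher, 6 were lower and 6 did not pass. Reg4 (log2 fold change -2.64 ± 0.34, SE) and Ang4 (-2.57 ± 0.32) were among the lower ones. Of 22 goblet cell genes, 3 were lower and 19 did not pass. Of 20 crypt stem cell genes, 7 were lower and 13 did not pass, with Lgr5 (-1.68 ± 0.28), the Wnt-responsive stem cell receptor, at 4.53 ± 2.37 CPM in DKO (7.22, 3.65 and 2.72 in replicates 1 to 3) and 14.5 ± 1.37 in WT, and Smoc2 at -1.84 ± 0.18. Of 30 cell cycle genes, 20 did not pass and 10 were lower, among them the replication helicase genes Mcm5 (-1.14 ± 0.20) and Mcm6 (-0.97 ± 0.15). With p-values adjusted over the list alone, 7, 4, 7 and 12 genes of these lists were lower, and 2 deep crypt secretory genes were higher. With camera of limma the lists passed at adjusted p = 0.000308, 0.00648, 0.00454 and 4.58e-07. None passed with an estimated correlation, where adjusted p = 0.280 for deep crypt secretory cells and 0.423 for the other lists. With fry the cell cycle list did not pass (adjusted p = 0.0579) and the other 3 did. The goblet cell list lost its call without DSS DKO replicate 1 (adjusted p = 0.0540). The goblet and deep crypt secretory lists share Agr2, Spink4, Retnlb and Ang4. Among 24 Wnt target genes, 3 were lower and 21 did not pass, and 3 were lower adjusted over the list alone. The Wnt target list did not pass camera (adjusted p = 0.165) or fry (0.256).

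Of 28 absorptive colonocyte genes, 8 were higher and 1 lower in DKO after DSS, with Alpi (intestinal alkaline phosphatase, log2 fold change 1.44 ± 0.18, SE) and Scnn1b (a subunit of the epithelial sodium channel, 1.48 ± 0.19) higher, and the list did not pass camera (adjusted p = 0.0931). Adjusted over the list alone, 9 were higher and 6 lower. Of 20 enteroendocrine genes, 3 were higher and 1 lower, and 9 and 2 adjusted over the list alone. Chga (1.67 ± 0.21), the general marker of these cells, was higher, and Insl5 (-1.70 ± 0.22), a hormone of these cells, was lower. The enteroendocrine list passed camera at adjusted p = 0.0147, but not with an estimated correlation (adjusted p = 0.423), without DSS WT replicate 1 (0.0668) or without DSS DKO replicate 3 (0.0534). Of 19 tuft cell genes, 3 were lower and 16 did not pass, 2 were higher and 3 lower adjusted over the list alone, and the list did not pass camera (adjusted p = 0.596).

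Of 31 interferon-gamma response genes, 17 were lower in DKO after DSS, 0 higher and 14 did not pass, with a median log2 fold change of -0.98. Tgtp2 (-2.63 ± 0.29, SE) and Irgm2 (-1.14 ± 0.13), both interferon-inducible GTPases, and Psmb9 (-1.30 ± 0.16), an immunoproteasome subunit, were examples. Of 32 type I interferon genes, 9 were lower and 23 did not pass, with Bst2 at -1.13 ± 0.23. Of 16 MHC class I genes 8 were lower, and of 11 MHC class II genes 4 were lower, including H2-Eb1 (-1.92 ± 0.41). With p-values adjusted over the list alone, the lower genes were 25, 13, 8 and 8. Camera gave adjusted p = 8.33e-13, 7.89e-09, 0.000625 and 7.72e-05. With an estimated correlation no list passed (adjusted p = 0.280, 0.423, 0.423 and 0.386), and with fry the type I interferon list did not pass (adjusted p = 0.0513) and the other 3 did. The call of H2-Eb1 was lost without DSS WT replicate 2 (adjusted p = 0.0554). These lists share genes, such as Psmb9, Tap1 and Nlrc5 (interferon-gamma and MHC class I) and Ciita (interferon-gamma and MHC class II). Their results are therefore not independent.

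The Percoll step was meant to remove lymphocytes. Of 24 T cell, intraepithelial lymphocyte and natural killer cell genes, 14 were lower in DKO after DSS, 0 higher and 10 did not pass, with a median log2 fold change of -1.26. Gzma, a protease of cytotoxic cells, was at 13.7 ± 3.91 CPM in DSS DKO and 47.4 ± 4.49 in DSS WT (SD, n = 3 each). Of 16 neutrophil genes, 6 were higher, 0 lower and 10 did not pass, with Ly6g (2.10 ± 0.17, SE) at 131 ± 15.9 and 30.4 ± 7.46 CPM and the collagenase gene Mmp8 at 2.83 ± 0.36. Of 19 macrophage and dendritic cell genes 1 was lower and of 13 B and plasma cell genes 1 was lower. Adjusted over the list alone, 20 T cell genes were lower, 6 neutrophil genes higher, 0 macrophage genes and 1 B cell gene lower. The T cell list (adjusted p = 5.01e-11), the neutrophil list (5.34e-05) and the B cell list (0.0147) passed camera, and the macrophage list did not (0.680). With an estimated correlation the adjusted p = 0.325 for T cells, 0.280 for neutrophils and 0.514 for B cells. The B cell list also did not pass fry (adjusted p = 0.246) and lost its call without DSS WT replicate 2 (0.277), where its mean log2 fold change went from -0.99 to -0.36, without DSS DKO replicate 1 (0.0998) and without DSS DKO replicate 3 (0.0566). The call of Gzma was lost without DSS DKO replicate 2 (adjusted p = 0.0693).

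Of 27 matrix remodelling genes, 11 were higher in DKO after DSS, 0 lower and 16 did not pass, and of 27 regeneration genes (fetal-like and YAP targets) 7 were higher and 1 lower. Of the regeneration genes, Ly6c1 had a log2 fold change of 2.45 ± 0.28 (SE). Of 24 IL-22 and STAT3 response genes 5 were higher and 1 lower, with Lcn2, a siderophore-binding defence protein, at 2.69 ± 0.32. Of 29 TNF and NF-kB response genes 4 were higher and 0 lower, with the chemokine gene Cxcl1 at 1.57 ± 0.32. With p-values adjusted over the list alone, 15, 11, 5 and 5 genes were higher, and 0, 1, 1 and 0 lower. Camera gave adjusted p = 8.04e-08, 0.000629, 0.00454 and 0.00454, and with an estimated correlation adjusted p = 0.264, 0.280, 0.423 and 0.423. The call of Cxcl1 was lost without DSS DKO replicate 2 (adjusted p = 0.0502), and those of the IL-22 and STAT3 list and the TNF and NF-kB list without DSS DKO replicate 1 (0.105 and 0.0788). With fry the IL-22 and STAT3 list did not pass (adjusted p = 0.0579) and the other 3 did. Of 19 fibroblast genes, 4 were higher and 1 lower, and 5 and 3 adjusted over the list alone. The fibroblast list did not pass camera (adjusted p = 0.651).

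Of 27 genes of fatty acid oxidation and ketogenesis, 11 were higher in DKO after DSS, 1 lower and 15 did not pass, with Angptl4 (log2 fold change 3.96, a PPAR target) and Acot2 (1.45 ± 0.25, SE), a mitochondrial thioesterase. Of 25 cholesterol synthesis genes, 17 did not pass and 8 were lower, among them Tm7sf2 (-1.30 ± 0.19) and Dhcr7 (-0.82 ± 0.14). Of 26 unfolded protein response genes, 10 were lower and 2 higher, with the chaperone genes Hsp90b1 (-0.88 ± 0.13), Pdia4 (-0.93 ± 0.14) and Sdf2l1 (-1.18 ± 0.19) lower. Adjusted over the list alone, 14 fatty acid genes were higher and 1 lower, 13 cholesterol genes lower, and 11 unfolded protein response genes lower and 2 higher. Camera gave adjusted p = 4.79e-05, 8.45e-05 and 0.0200, and with an estimated correlation adjusted p = 0.423 for each. With fry the fatty acid and cholesterol lists did not pass (adjusted p = 0.0579 and 0.0573) and the unfolded protein response list did (0.0301). Of 22 bile acid and nutrient transport genes 6 were higher and 4 lower, 8 and 5 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.135), with the bile acid exporter subunit Slc51a at 1.73 ± 0.20, the transferrin receptor Tfrc at -0.84 ± 0.12 and the monocarboxylate transporter Slc5a8 at -1.37 ± 0.12.

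Of 39 published miR-181 targets measured, 2 were higher in DKO after DSS, 4 lower and 33 did not pass, and camera gave adjusted p = 0.866. With p-values adjusted over the list alone, 3 were higher and 5 lower. Cbx7, a Polycomb protein, was at 34.2 ± 3.91 CPM in DSS DKO and 11.7 ± 3.38 in DSS WT (SD, n = 3 each; log2 fold change 1.54 ± 0.18, SE). Atm (-1.02 ± 0.20), Hspa5 (-0.58 ± 0.13), S1pr1 (-1.52 ± 0.41) and Atg5 (-0.46 ± 0.13) were lower. Hspa5 is also on the list of neighbours of the miR-181 loci. Without DSS DKO replicate 2 the calls of Atm, Hspa5, S1pr1 and Atg5 were lost (adjusted p = 0.0570, 0.0810, 0.126 and 0.168), and without DSS WT replicate 3 those of Hspa5 and Atg5 (0.0734 and 0.123). Without DSS WT replicate 2 those of Hspa5, S1pr1 and Atg5 were lost (0.0611, 0.174 and 0.132), without DSS WT replicate 1 that of Atg5 (0.0922), and without DSS DKO replicate 3 those of S1pr1 and Atg5 (0.0517 and 0.0708). That of S1pr1 was also lost in a fit to the 6 DSS libraries alone (0.0681). Those of S1pr1 and Atg5 were lost without DSS DKO replicate 1 (0.0614 and 0.0536), and that of Atg5 without baseline DKO replicate 1, 2 or 3 (0.0545, 0.0581 and 0.0567). Of 14045 tested genes with a 3' UTR of at least 100 bases, 3323 held a miR-181 seed site. The mean log2 fold change of genes with a site minus that of genes without was -0.05 after DSS and -0.04 at baseline, and neither passed limma's camera at an unadjusted 0.05. For 100 shuffled 7-mers the same difference ranged from -0.131 to -0.0383 after DSS and from -0.0695 to -0.0193 at baseline.

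**Figure D2:**
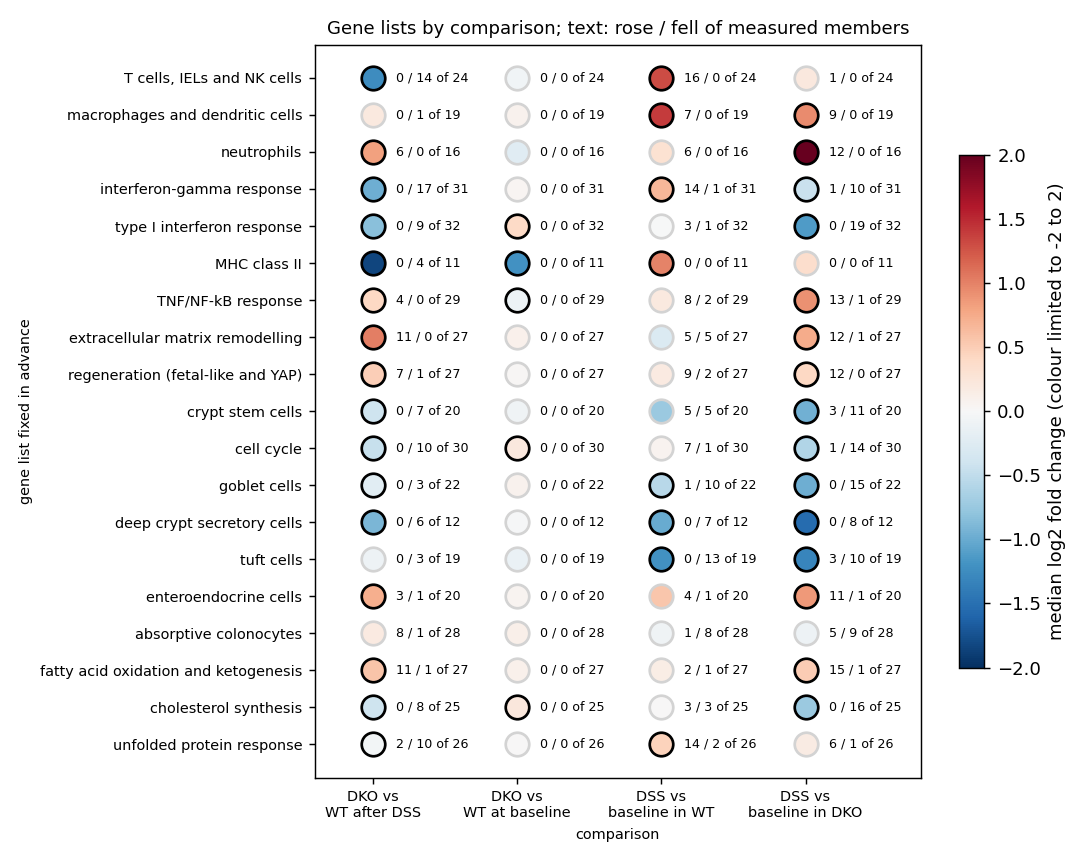
Median log2 fold change (colour) of 19 gene lists in 4 comparisons, with the numbers of members that rose and fell of those measured, and a black outline where camera gave an adjusted p under 0.05 at the preset correlation. In DKO against WT after DSS, 14 of 24 T cell genes and 17 of 31 interferon-gamma genes are lower and 6 of 16 neutrophil genes are higher.

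Of the 45 lists, 22 passed camera after DSS, 15 of these also passed fry and 0 passed with an estimated correlation (lowest adjusted p = 0.264). Both the 22 and the 15 include the sex-linked list, in which the 4 genes that passed were Y-linked genes at trace levels. Several lists share genes, so the lists that passed are not independent of one another. Leaving out DSS WT replicate 2, DSS WT replicate 3 or DSS DKO replicate 2 lowered the 2165 genes to 856, 866 and 691, fitting the 6 DSS libraries alone gave 1372, and a 2-fold minimum gave 926.

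At baseline, DKO and WT epithelium differed in 5 genes of 19267, 2 higher and 3 lower in DKO. Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase, was at 68.3 ± 10.8 CPM in baseline DKO (SD, n = 3) and 26.5 ± 0.871 in baseline WT (SD, n = 2). Wdfy1, an endosomal adaptor, was at 78.1 ± 2.10 and 35.5 ± 1.81 CPM. Tmem254 was at 39.8 ± 4.79 and 143 ± 14.8 CPM, Sprr2a2, a cornified envelope gene, at 10.8 ± 0.366 and 27.8 ± 6.50, and Duxbl1, a homeobox gene, at 0.358 ± 0.0718 and 2.66 ± 0.331. Duxbl1 lies outside the naming rule and was named after its values were seen.

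The log2 fold changes at baseline were 1.37 ± 0.14 for Nnt (SE), 1.14 ± 0.15 for Wdfy1, -1.85 ± 0.13 for Tmem254, -1.36 ± 0.19 for Sprr2a2 and -2.90 ± 0.31 for Duxbl1. Their adjusted p-values in the edgeR test were 0.00530, 0.0263, 8.90e-05, 0.0420 and 0.00530. All 5 genes differed in the same direction after DSS, with log2 fold changes of 1.02, 1.90, -2.23, -1.18 and -3.22. Nnt lies on chromosome 13 from 119335448 to 119408997, Wdfy1 on chromosome 1 from 79702262 to 79776143, Sprr2a2 on chromosome 3 from 92215920 to 92256724 and Duxbl1 on chromosome 14 from 25978577 to 25990088. The symbol Tmem254 has no position in the annotation used. Without baseline WT replicate 1 or replicate 2 only Tmem254 passed, and Nnt had adjusted p = 0.131 and 0.0808, Wdfy1 0.376 and 0.346, Sprr2a2 0.0963 and 0.714, and Duxbl1 0.0599 and 0.0808. The calls of Wdfy1 and Sprr2a2 were also lost without baseline DKO replicate 1 (0.128 and 0.305), 2 (0.164 and 0.218) or 3 (0.105 and 0.285), DSS WT replicate 3 (0.0752 and 0.102) or DSS DKO replicate 2 (0.0785 and 0.123). That of Duxbl1 was also lost without baseline DKO replicate 2 (0.0699) or 3 (0.0582), and that of Sprr2a2 without DSS WT replicate 1 (0.0770) or 2 (0.0954).

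No gene list had a member past the test at baseline, and adjusted over the list alone 1 of 19 fibroblast genes was higher. With camera, 10 of 45 lists passed, 7 higher and 3 lower in DKO, but 0 passed fry and 0 passed with an estimated correlation (lowest adjusted p = 0.906). The list medians were 0.40 for 32 type I interferon genes, 0.21 for 30 cell cycle genes, 0.23 for 25 cholesterol synthesis genes and -1.22 for 11 MHC class II genes. These 4 lists lost their call without baseline WT replicate 1, where their mean log2 fold changes went from 0.36 to 0.07, from 0.19 to 0.10, from 0.23 to 0.07 and, reversed, from -0.97 to 0.12 (adjusted p = 0.981, 0.589, 0.770 and 0.751). The type I interferon list also lost it without baseline DKO replicate 1 (mean 0.02, adjusted p = 0.735) and the cell cycle list without baseline DKO replicate 3 (mean 0.12, adjusted p = 0.0795). At an unadjusted p under 0.05 there were 751 genes, fewer than the 963 expected by chance, and DESeq2 called 15 genes and limma-voom 5. Leaving out both baseline DKO libraries with much ribosomal RNA, an alternative chosen after seeing the data, left 1 gene.

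In WT, the lists of goblet and tuft cell genes were lower in DSS than in baseline libraries, and those of T cell, interferon-gamma and macrophage genes higher, by camera at its preset correlation and not at an estimated one. Muc2, the main mucin of the colon, was at 1685 ± 263 CPM in DSS WT (SD, n = 3) and 12650 ± 4713 in baseline WT (SD, n = 2). Reg3b, an antimicrobial lectin gene, was at 467 ± 47.8 and 25.1 ± 2.50 CPM. The groups differed in sex as well as in treatment, so the part of each is not separated here. By edgeR's quasi-likelihood test 6432 genes passed, 3260 higher and 3172 lower after DSS. With a 2-fold minimum, 929 were higher and 2133 lower.

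Among genes that met the naming rule in WT, large increases besides Xist (log2 fold change 6.91 ± 0.33, SE) were those of the cytokine Il1b (5.64 ± 0.48), the mast cell proteases Mcpt2 (5.42 ± 0.79) and Mcpt1 (4.92 ± 0.86), Clca4b (4.33 ± 0.55), Reg3b (4.22 ± 0.65), the heat shock protein gene Hsph1 (3.56 ± 0.61), Reg3g (3.02 ± 0.40) and Srgn (2.96 ± 0.43). After the Y-linked genes Kdm5d (-6.79), Eif2s3y (-6.67) and Ddx3y (-6.12), large decreases were those of Pnliprp2 (-5.00 ± 0.57), Ang4 (-4.88 ± 0.36), the clock gene Nr1d1 (-4.86 ± 0.21), Pla2g4c (-4.53 ± 0.37), the mucus protein gene Fcgbp (-4.05 ± 0.69) and AI838599 (-3.68 ± 0.32). Adjusted p-values in the edgeR test were 0.00316 or lower for each of these genes.

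Of 22 goblet cell genes in WT, 10 fell and 1 rose, with Muc2 at -2.91 ± 0.22 (log2 fold change, SE) and Clca1 at -2.74 ± 0.18, and of 19 tuft cell genes 13 fell and 0 rose, with Sh2d6 (-3.30 ± 0.28), Trpm5 (-2.30 ± 0.41) and Dclk1 (-1.68 ± 0.27). Of 24 T cell genes 16 rose and 0 fell, with Gzma at 2.89 ± 0.45, of 31 interferon-gamma genes 14 rose and 1 fell, and of 19 macrophage genes 7 rose and 0 fell, with Cd14 at 1.40 ± 0.17. Of 26 unfolded protein response genes 14 rose and 2 fell, with Hspa5 (1.49 ± 0.16) and Sdf2l1 (1.70 ± 0.22), and of 30 oxidative phosphorylation genes 13 rose and 0 fell. Of 27 regeneration genes 9 rose and 2 fell, with Ly6a (1.59 ± 0.20) and Mmp7 (2.97 ± 0.42), and the list did not pass camera (adjusted p = 0.0946). Adjusted over the list alone, 11 goblet and 15 tuft genes fell, and 17 T cell, 16 interferon-gamma, 11 macrophage, 15 unfolded protein response, 13 oxidative phosphorylation and 9 regeneration genes rose. Of 27 antimicrobial and mucosal defence genes, which include Reg3b, 6 rose and 6 fell, also when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.346). The smooth muscle list, of cells outside the epithelium, was lower (mean log2 fold change -1.30, camera adjusted p = 0.0162). In all, 14 of 45 lists passed camera, the sex-linked list included, and 0 with an estimated correlation (lowest adjusted p = 0.388). The count of 6432 genes was 2775 without baseline WT replicate 1, 4257 without baseline WT replicate 2, 4163 without DSS WT replicate 2, 4088 without DSS WT replicate 3 and 3062 with a 2-fold minimum.

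In DKO, the lists of goblet, deep crypt secretory and type I interferon genes were lower in DSS than in baseline libraries, and those of neutrophil and enteroendocrine genes higher, by camera at its preset correlation and not at an estimated one. Clca1 was at 233 ± 33.6 CPM after DSS and 15900 ± 2590 at baseline (SD, n = 3 each), Mptx1 at 4.64 ± 1.45 and 3540 ± 1262, and Reg3b at 2603 ± 1266 and 44.6 ± 31.7. By edgeR's quasi-likelihood test 4545 genes passed, 2430 higher and 2115 lower after DSS. With a 2-fold minimum, 850 were higher and 1255 lower. Here too sex differed along with treatment.

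Among genes that the naming rule takes by size of change in DKO, the largest increases after Xist (log2 fold change 6.12 ± 0.27, SE) were those of Reg3b (5.87 ± 0.59), Clca4b (5.81 ± 0.50), Il1b (5.18 ± 0.40), Angptl4 (5.11 ± 0.69), Saa3 (4.87 ± 0.55), Ly6c1 (4.64 ± 0.31), the protease inhibitor gene Slpi (4.20 ± 0.40), the calcium-binding protein gene S100g (4.17 ± 0.76) and Reg3g (4.07 ± 0.36). Besides the Y-linked Kdm5d (-9.94), Eif2s3y (-8.10) and Ddx3y (-8.00), the decreases were those of Mptx1 (-9.57 ± 0.44), Ang4 (-7.38 ± 0.40), Clca1 (-6.09 ± 0.20) and Pla2g4c (-6.09 ± 0.39). Mir6236 (-7.09), Rn18s-rs5 (-6.54) and Lars2 (-6.08) also fell, and Rn18s-rs5 was high in 2 of the 3 baseline DKO libraries. Mir6236 and the protein-coding gene Lars2 were grouped here with Rn18s-rs5 as ribosomal RNA entries, but whether their reads come from ribosomal RNA was not tested. They varied as widely in baseline DKO (950 ± 969 and 4159 ± 5418 CPM, SD, n = 3), so these falls need not be a response to DSS. Adjusted p-values in the edgeR test were 0.00780 or lower for each of these genes.

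Of 22 goblet cell genes in DKO, 15 fell and 0 rose, with Muc2 at -2.57 ± 0.21 (log2 fold change, SE), of 12 deep crypt secretory genes 8 fell and 0 rose, with Reg4 at -3.21 ± 0.35, and of 19 tuft cell genes 10 fell and 3 rose, with Dclk1 at -2.36 ± 0.26. Enteroendocrine genes, of another secretory lineage, went the other way, as 11 of 20 rose and 1 fell (camera adjusted p = 8.62e-05, and 0.176 with an estimated correlation), and 13 rose and 1 fell adjusted over the list alone. Of 24 Wnt target genes 11 fell and 1 rose, with Lgr5 at -1.64 ± 0.28. Of 16 neutrophil genes 12 rose and 0 fell, with Ly6g (2.76 ± 0.17) and Mmp8 (3.19 ± 0.37), and of 29 TNF and NF-kB genes 13 rose and 1 fell, with the chemokine genes Cxcl2 (6.76 ± 0.69) and Cxcl1 (4.68 ± 0.40). Of 32 type I interferon genes 19 fell and 0 rose, with Oas1a at -1.11 ± 0.18, and of 25 cholesterol synthesis genes 16 fell and 0 rose, with Tm7sf2 (-1.41 ± 0.19) and Hmgcs1 (-1.24 ± 0.18). Of 27 regeneration genes 12 rose and 0 fell, with Plaur at 1.88 ± 0.20, and of 22 transport genes 11 rose and 3 fell, with Slc10a2 at 3.18 ± 0.30. Of 24 T cell genes 1 rose and 0 fell, and the list did not pass camera (adjusted p = 0.454). With p-values adjusted over the list alone, 16 goblet, 10 deep crypt secretory, 11 tuft, 11 Wnt target, 25 type I interferon and 20 cholesterol genes fell, and 12 neutrophil, 17 TNF and NF-kB, 12 regeneration, 12 transport and 0 T cell genes rose. The endothelium list, of cells outside the epithelium, was lower (mean log2 fold change -1.02, camera adjusted p = 0.00391). In all, 24 of 45 lists passed camera, the sex-linked list included, and 0 with an estimated correlation (lowest adjusted p = 0.108). The count of 4545 genes was 2605 without baseline DKO replicate 2, 2987 without DSS DKO replicate 2, 2105 with a 2-fold minimum, and 957 without both baseline DKO libraries with much ribosomal RNA, an alternative chosen after seeing the data.

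**Figure D3:**
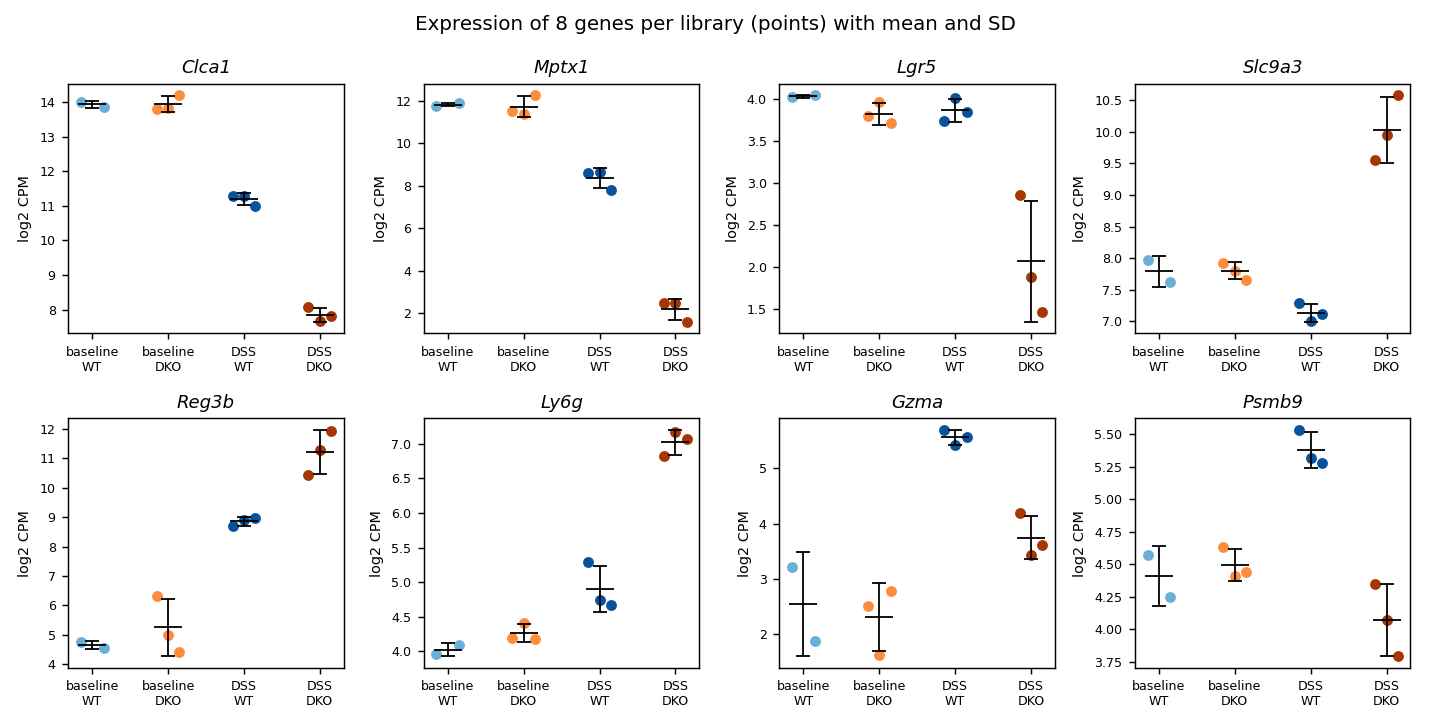
Log2 CPM of 8 genes, with 1 point per library, the mean as a horizontal bar and the SD as error bars, for baseline WT (n = 2), baseline DKO, DSS WT and DSS DKO (n = 3 each). Clca1 and Mptx1 are lower in DSS DKO than in DSS WT in every library, and Slc9a3, Reg3b and Ly6g are higher.

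The change from baseline to DSS libraries was compared between the genotypes, which share no libraries. Sex differed along with treatment in both genotypes, so the part of sex is not separated in the shared changes or in the interaction. Across 19267 genes, which are not independent replicates, log2 fold changes in DKO and WT had r = 0.54 and rho = 0.58. Genes that rose in both numbered 1369 (411 expected of independent lists), genes that fell in both 1277 (348 expected), and 51 moved in opposite directions. The interaction of genotype and treatment passed for 302 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 149 positive and 153 negative. Among the 10 with the lowest p were Clca1 (log2 difference of the responses -3.35 ± 0.25, SE), Mptx1 (-6.14 ± 0.52), the sialyltransferase gene St3gal1 (1.89 ± 0.21), Slc9a3 (2.95 ± 0.32), Slc5a8 (-1.42 ± 0.17), Cd177 (-2.18 ± 0.28), the phosphate transporter gene Slc34a2 (-2.33 ± 0.30), Nxpe2 (-1.87 ± 0.24) and Ly6g (1.86 ± 0.24), with adjusted p from 0.000253 to 0.0106. Slc9a3 rose in DKO after DSS (2.29 ± 0.23, adjusted p = 9.46e-05), while its value in WT was -0.66 ± 0.24 and did not pass (adjusted p = 0.0514). The fall in WT did pass without DSS WT replicate 1 (0.0493), without DSS DKO replicate 1 (0.0136) and without DSS DKO replicate 3 (0.00631), in a fit to the 5 WT libraries alone (0.0101), with DESeq2 (0.0390) and with the replicate number as a block (0.0461).

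The number of interaction genes depended on the baseline WT libraries. Without replicate 1 of baseline WT, 2 genes passed, and Mptx1, Slc9a3, Slc5a8, Cd177, Slc34a2, Nxpe2 and Ly6g had adjusted p between 0.0544 and 0.0621, and without replicate 2, 18 genes passed, with adjusted p = 0.0543 for Slc34a2, Nxpe2 and Ly6g. Leaving out baseline DKO replicate 1, 2 or 3 gave 125, 146 and 98 genes, DSS WT replicate 2 or 3 gave 74 and 60, DSS DKO replicate 1 or 2 gave 1498 and 43, and DESeq2 gave 1269.

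**Figure D4:**
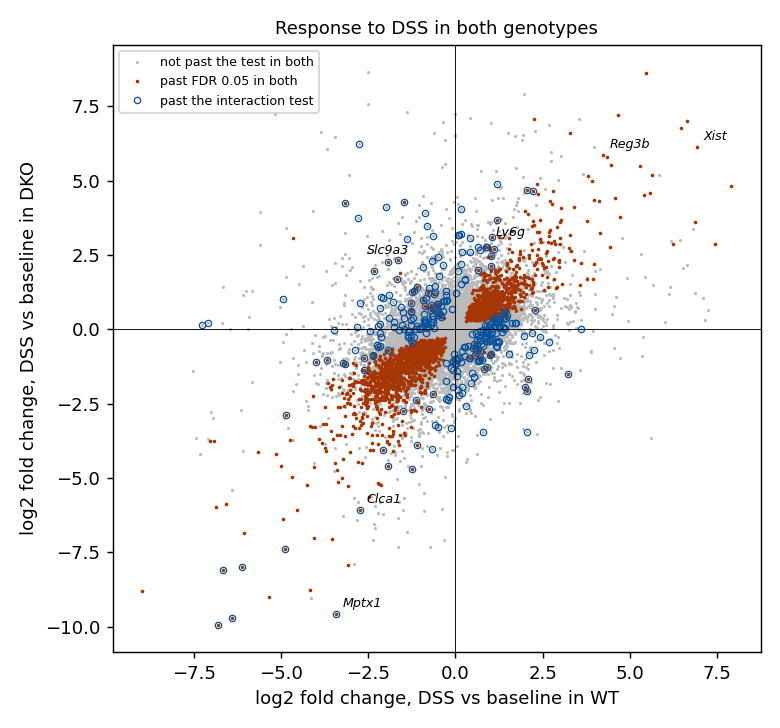
Log2 fold change of DSS against baseline in WT (x axis) and in DKO (y axis) for 19267 genes, with genes past the test in both genotypes in brown and genes past the interaction test circled in blue. Most genes past the test in both lie in the quadrants of shared direction (1369 higher, 1277 lower), and Clca1 and Mptx1 fell further in DKO.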

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

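The tests on X- and Y-linked genes and on leukocytes of every kind, and the fits without both baseline DKO libraries rich in ribosomal RNA, were chosen after the result was seen.

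The change from baseline to DSS libraries differed between the genotypes by the interaction term, the test of the difference itself. It passed for 302 genes and 18 of 45 gene lists, the sex-linked list included. Of these lists 7 passed fry and 0 passed with an estimated correlation. Sex differed along with treatment, so an interaction of genotype with sex cannot be told apart from one with DSS. The interaction log2 values were -3.35 for Clca1, -6.14 for Mptx1, 1.89 for St3gal1, 2.95 for Slc9a3, -1.42 for Slc5a8, -2.18 for Cd177, -2.33 for Slc34a2, -1.87 for Nxpe2 and 1.86 for Ly6g. Without baseline WT replicate 1, 2 genes passed (Mptx1 and Slc9a3 then had adjusted p = 0.0544 in edgeR's quasi-likelihood test), and without replicate 2, 18 passed.

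The differences between DSS and baseline libraries could come from treatment, from sex or from the hour of sampling. Xist and 4 Y-linked genes all passed in the direction that a difference of sex predicts, in both genotypes. Sex was itself read from genes among these 5, so this restates the pattern and is no separate test. For autosomal genes sex and treatment cannot be told apart, because 0 sexes are shared by baseline and DSS libraries, and the effect of DSS itself stays open as well. For a shift in the hour, clock genes of the phase opposite to Nr1d1 were compared with those in phase. They lay above by 1.28 in WT and 0.47 in DKO (log2, bootstrap SD 0.702 in DKO). The value in DKO was under the bound set beforehand against a shift, but by less than its bootstrap SD. A shift in the hour therefore stays open. Of the 10 splits of the 6 DKO libraries, 1 gave as many genes as the real 4545 (highest other 3) and 1 as many lists as the real 24 (highest other 19), and 10 splits are too few for a share under 0.05.

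The 5 genes that differed between DKO and WT at baseline may reflect a difference of strain background, since all 5 differed in the same direction after DSS. By chance 0.281 were expected, if the 5 are taken as independent. Tmem254 and Duxbl1 may not be, and both comparisons share the dispersion estimate. The same 5 argue against ribosomal RNA carry-over in 2 baseline DKO libraries, because that share was low in every DSS library. Flanking DNA of the targeted loci is argued against only for the 4 called genes with a position. Within 20 Mb of a miR-181 cluster there were 0 of them, though Wdfy1 shares chromosome 1 with the first cluster. Among 19 measured neighbours of the miR-181 loci, 0 passed at baseline, and 2, Hspa5 included, were lower in DKO after DSS. After DSS that list did not pass camera (adjusted p = 0.103) but passed fry (0.0222), so flanking DNA stays open for genes near the loci. A direct effect of the deletion predicts that the 5 genes differ after DSS too, so it stays open, and no strain label separates it. A difference of background, if present, would enter every comparison of DKO with WT, the calls after DSS included. Copies of Tmem254 and Duxbl1 lie interleaved on chromosome 14 from 25923300 to 26269436, so reads shared between copies also stay open for these genes.

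The lower T cell and interferon-gamma genes in DKO after DSS could reflect fewer T cells left after the Percoll step, or a lower interferon response of the epithelium. Fewer leukocytes of every kind is argued against by a median neutrophil log2 fold change of 0.82, with 6 markers higher and 0 lower. This holds only if these genes mark neutrophils in the epithelial fraction, which was not tested. Leukocytes as a whole could still be fewer. Ptprc, a general leukocyte gene, was at 41.8, 54.1 and 39.9 CPM in the DSS WT libraries. In the DSS DKO libraries Ptprc was at 30.5, 17.2 and 14.4 CPM, but it also lies near a miR-181 locus. RNA of the T cells themselves as the source of the interferon-gamma genes cannot be told apart from a response of the epithelium. The summed interferon-gamma CPM was 1239 ± 127 in DSS WT and 781 ± 111 in DSS DKO (SD, n = 3 each), a fall of 2.45 times the T cell marker sum of 187 ± 11.6 CPM in DSS WT, but the smallest fall between any pair, 227 CPM, exceeded that sum by less than the SD of 169. Of the 10 splits of the 6 DSS libraries, 1 gave as many genes as the real 2165 (highest other 1290, which points to a structure of the samples) and 2 as many lists as the real 22 (highest other 22), and 10 splits are too few for a share under 0.05.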

How the results depend on the processing

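The fits without both baseline DKO libraries rich in ribosomal RNA, without ribosomal RNA entries and without X and Y genes were chosen after seeing the data. With an estimated correlation, 0 lists passed in DKO against WT after DSS, 0 at baseline, 0 in WT and 0 in DKO for DSS against baseline. With fry, 0 lists passed at baseline and 25 in WT. Without a filter, 79 genes passed at baseline and 1469 in the interaction, and with DESeq2 15 and 1269. A 2-fold minimum gave 926 genes after DSS, 3062 in WT and 2105 in DKO, by its stricter threshold. Fitting the 6 DSS libraries alone gave 1372 genes. Leaving out both baseline DKO libraries gave 1 gene at baseline, 957 for DSS in DKO and 86 in the interaction, with fewer samples. The seed-site difference after DSS reversed to 0.00911 when adjusted for 3' UTR length and GC content, and did not pass. The correlation of the DSS responses was 0.744 for genes with a mean log2 CPM of at least 3. The causes of the other changes were not tested.

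Leaving out each library in turn gave 691 to 3064 genes after DSS, 1 to 5 at baseline, 2775 to 7378 in WT, 2605 to 5788 in DKO and 2 to 1498 in the interaction. Lists past the threshold ranged from 18 to 25, 2 to 10, 11 to 17 and 24 to 32 in the first 4 of these. The seed-site difference ranged from -0.0834 to -0.0139 after DSS and from -0.0583 to -0.0265 at baseline, where it passed limma's camera without baseline DKO replicate 1 (-0.0518) or 2 (-0.0425). The correlation of the responses ranged from 0.416 to 0.562. At baseline, the mean log2 fold change of the MHC class II list was -0.97 and ranged from -1.47 to 0.12, reversed without baseline WT replicate 1. That of the TNF and NF-kB list was -0.49 and ranged from -0.649 to 0.0341, reversed without the same library, and that of the oxidative phosphorylation list was 0.11 and ranged from -0.0489 to 0.233, reversed without baseline DKO replicate 3.

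Whether the replicate numbers pair the samples stays open. Deviations of same-numbered DSS libraries of the genotypes correlated at 0.302, 0.0194 and 0.201. Those numbered 1 and those numbered 3 each correlated best with one another. Same-numbered baseline libraries of the genotypes correlated at 0.141 and -0.0705. With the replicate number as a block, 3 genes and 6 lists passed at baseline, the seed-site difference there was -0.0573 and passed limma's camera, and Mmp13 (adjusted p = 0.0999) and S1pr1 (0.0515) after DSS and Wdfy1 (0.0509) and Sprr2a2 (0.164) at baseline no longer passed in edgeR's test. The named genes past the test for DSS against baseline in WT and in DKO kept their direction and call with DESeq2, DESeq2 size factors, the block, the 2-group fit and each library left out. Slc9a3 in WT, which did not pass, passed in 6 of its 15 alternatives. After DSS, the log2 fold change of Hoxa13 (0.00) reversed to -0.00665 with DESeq2 size factors, -0.0139 with DESeq2, -0.231 with the block and -0.0110 in the 2-group fit, and ranged from -1.15 to 0.469 with each library left out. That of Hoxb4 (0.15) ranged from -0.0112, without DSS DKO replicate 1, to 0.383. Genes with few counts, such as Mir181a-1hg with 4 to 31, are limited by depth.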

Other observations

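The tests of seed-site release and of Y-linked genes in DSS DKO were chosen after their results were seen, the Hox genes were singled out after their values were seen, and the other tests here were written before.

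Of 10 genes of the proximal colon, 5 were lower in DKO than in WT after DSS, 1 higher and 4 did not pass, and adjusted over the list alone 5 were lower and 2 higher. The list passed camera at adjusted p = 0.00681, but adjusted p = 0.325 with an estimated correlation, and it shares Mptx1, Ang4 and Insl5 with other lists. Insl5, 1 of the 5 lower genes, was placed on this list beforehand, and its place along the colon is uncertain. Of 10 genes of the distal colon, 1 was higher and 0 lower (adjusted p = 0.249). Hoxb13, a homeobox gene of the distal colon, was at 126, 97.9 and 69.8 CPM in the DSS WT libraries and at 80.5, 35.8 and 11.8 CPM in the DSS DKO libraries, against 107 to 136 CPM in the baseline libraries. Hoxd13 was at 32.8, 26.7 and 15.1 CPM in the DSS WT libraries and at 19.4, 4.82 and 0.454 CPM in the DSS DKO libraries, against 18.7 to 37.1 CPM in the baseline libraries. In DKO against WT after DSS, 0 of 6 posterior Hox genes passed: Hoxb13 (log2 fold change -1.19 ± 0.54, SE, adjusted p = 0.191), Hoxd13 (-1.59 ± 0.89, 0.293), Hoxd12 (-2.99 ± 0.89, 0.0555), Hoxd11 (-1.19 ± 0.81, 0.382), Hoxd10 (-1.87 ± 0.69, 0.109) and Hoxa13 (0.00 ± 0.62). Without DSS DKO replicate 1, Hoxb13, Hoxd13, Hoxd12 and Hoxd10 passed, at log2 fold changes of -2.04, -3.22, -4.77 and -3.27 (adjusted p = 0.00794, 0.0142, 0.0214 and 0.00879). Hoxd12 also passed without DSS WT replicate 3 (0.0343) and with the replicate number as a block (0.0176), and Hoxd12 and Hoxd10 passed with DESeq2 (0.00197 and 0.0180). Of 4 anterior Hox genes, Hoxb5 was higher (0.80 ± 0.20, adjusted p = 0.0248), and Hoxb6 (0.59 ± 0.21, 0.101), Hoxb4 (0.15 ± 0.23) and Hoxa4 (-0.68 ± 0.42) did not pass. The call of Hoxb5 was lost without DSS WT replicate 2 (0.108) or 3 (0.107), without DSS DKO replicate 2 (0.119) and in a fit to the 6 DSS libraries alone (0.0852), and Hoxb6 passed without DSS DKO replicate 3 (0.0118). Lgr5 fell from DSS DKO replicate 1 to 3 in the same order as Hoxb13 and Hoxd13 (7.22, 3.65 and 2.72 CPM), but not in DSS WT (13.28, 15.99 and 14.35 CPM). Slc9a3 (751, 985 and 1529 CPM) and Reg3b (1385, 2513 and 3911 CPM), picked after their values were seen, rose over these DKO replicates. In DSS WT Reg3b also rose (414, 480 and 506 CPM) and Slc9a3 did not (156, 128 and 139 CPM). Whether the same stretch of colon was sampled in both genotypes after DSS stays open.

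Of 30 oxidative phosphorylation genes, 1 was lower in DKO after DSS and 29 did not pass, with a median log2 fold change of -0.21 (camera adjusted p = 0.00454, adjusted p = 0.562 with an estimated correlation, and 0.252 with fry). Adjusted over the list alone, 0 passed, and the list lost its call without DSS DKO replicate 1 (adjusted p = 0.132). Of 8 mitochondrially encoded genes, 0 passed in this comparison (camera adjusted p = 0.460). In each genotype 5 of the 8 were lower after DSS than at baseline and 0 higher, 6 adjusted over the list alone, with medians of -0.70 in WT and -0.62 in DKO. Camera gave adjusted p = 0.0516 in WT and 0.0218 in DKO, and with an estimated correlation 0.586 and 0.474. In DKO the call was lost without baseline DKO replicate 3 (0.0586) or DSS DKO replicate 1 (0.0981). Only 8 of the 13 genes on the mitochondrial list were tested. Mitochondrial messenger RNA took 8.26% to 8.54% of the counts in baseline WT and 6.52% to 9.54% in DSS WT. Its share was 5.38% to 8.67% in baseline DKO and 7.17% to 8.62% in DSS DKO, so the ranges overlapped in both genotypes.

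A hypothesis was that loss of miR-181 may release genes with its seed site in the 3' UTR. The difference of mean log2 fold change, site minus no site, was -0.0497 after DSS, where release predicts a value above those of shuffled 7-mers. It lay inside the range of 100 of these (-0.131 to -0.0383, median -0.0768) yet above 96 of them, and at baseline 44 of them lay above -0.0428, so the test leaves the hypothesis open. Of the 10 splits of the 6 DSS libraries, 2 gave a difference as large in size (highest other 0.101), and 10 splits are too few for a share under 0.05.

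The trace counts of Y-linked genes in DSS libraries may come from reads or RNA carried over between libraries. In DSS WT, Ddx3y, Eif2s3y, Kdm5d and Uty were at 1.54%, 1.05%, 0.940% and 1.24% of their baseline levels, so the highest share was 1.64 times the lowest, near the single ratio that 1 source predicts. In DSS DKO the shares were 0.366%, 0.342%, 0.0914% and 0.0954%, and the highest was 4.001 times the lowest, further from a single ratio. The counts there were 0 to 16 per gene and library, so carry-over stays open in these libraries. If present, it could also make up part of low DSS DKO levels of genes high at baseline, such as Mptx1, whose fold changes are then uncertain. Xist in baseline WT and DKO was at 0.919% and 1.29% of its level after DSS.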
